A study of Rattus norvegicus with 24 samples.

How the data were processed

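Total RNA was sequenced from punches of the nucleus accumbens (NAc) and the ventral tegmental area (VTA) of Sprague Dawley rats given fentanyl or saline. The 24 libraries came from 14 rats of both sexes, and 10 rats gave a library from each region. Per the labels, RNA was purified on columns, ribosomal RNA was depleted and libraries were read as paired ends.

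The deposited tables hold raw counts per Ensembl rat gene, 1 table per library, with no normalization. The authors name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 in their processing notes, with no role or order. Genome build, annotation release, strand setting and the treatment of reads with several alignments are not given in the sources used here. Coordinates are those of the deposited tables. Features that overlap on opposite strands, or that have close paralogs, therefore carry an unknown share of each other's reads. The tables list 32552 genes, 27051 of them with a count in some library. Total counts were 3.46 M to 5.01 M in the 14 NAc libraries and 4.49 M to 6.3 M in the 10 VTA libraries.

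Groups were taken from the labels (region, sex, treatment), giving 8 groups of 2 to 4 rats. Counts of Y features matched the labelled sex in all 24 libraries, with 956 to 1772 in the 12 male and 9 to 41 in the 12 female libraries. No 2 libraries of a group were copies of each other: over the 26 pairs within groups, the chi-square per degree of freedom was 2.38 to 18.4 on genes with at least 50 counts. Libraries of a rat pair across regions by the animal code; the mean correlation of their residuals was 0.0397 over 10 pairs, against -0.00302 over 130 pairs from different rats. Whether the number in the animal code pairs rats within a region could not be told. Libraries with the same number had a mean residual correlation of -0.0146 over 12 NAc pairs and 0.00151 over 10 VTA pairs. The measure was weak: pairs from the same rat ran from -0.0465 to 0.161, and pairs from different rats from -0.145 to 0.164.

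Called genes come from edgeR 4.0.16 in R 4.3.3: scaling by TMM, a low-count filter (filterByExpr), robust dispersion, a quasi-likelihood fit with robust=TRUE and its two-sided F test, with Benjamini-Hochberg adjusted p under 0.05. Each region was fitted once with its 4 groups of sex and treatment, which share an estimate of the spread. The contrasts were fentanyl minus saline in males, in females and as their mean, the female effect minus the male effect, and saline females minus saline males. Regions were compared within the 10 rats that gave both, with rat as a block, and so was the difference of the fentanyl effect between regions in each sex. Standard errors of log2 fold changes were derived from the F statistic. Group values are CPM (counts scaled to a common library total) as mean ± SD. Log2 CPM used a prior count of 2, and the principal components used 2000 genes. Where a group had 0 counts, the ratio was taken against a floor of 3 counts over the group; with 1 to 3 counts it is given with its 95% exact counting interval. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

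The comparisons, tests, other settings and naming rule were fixed before the data were examined. The files pair no Ensembl ID with a name, so the 31 gene lists fixed beforehand and the genes to be named by symbol were not analysed here. The naming rule kept its other conditions, but fewer genes were kept per direction than fixed beforehand. It took called genes with a mean of at least 1 CPM and no overlap between the groups (a condition dropped for differences of effects). Of these, at most the 2 largest fold changes each way are given by ID. Where fewer than 5 genes were called, at most the 2 smallest unadjusted p each way are given as values only. Some of those picked for the VTA are not printed.

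In place of the lists, 26 sets defined by position or by region were chosen after the data were examined: 21 chromosomes, mitochondrial features of 200 nt or more, mitochondrial features under 100 nt, genes at least 4-fold higher in the VTA or in the NAc, and single-exon features under 500 nt. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks if the genes of a set move one way. Shares of counts were compared by exact two-sided permutation tests, with sexes kept apart where both were used, and adjusted by Benjamini-Hochberg over 6 comparisons. The sex difference in the mitochondrial share was tested by permuting sex within treatment. Signs of the genes called in NAc females were compared with other groups against every split of the libraries of those groups. Sex differences were counted in fentanyl and in saline rats of the NAc over the 16 fits that leave out 1 fentanyl rat of each sex. The splits of the female NAc libraries were counted again with all NAc libraries thinned to one depth. Short features were compared with longer ones by resampling them 10000 times. The place of a NAc library between saline and fentanyl females was taken from its log2 CPM over the same genes. These tests were likewise chosen after the data were examined. Local gene density was the number of listed genes within 1 Mb. Clusters of called genes were searched in windows of 1 Mb with at least 4 called genes, against 1000 shuffles of the calls, and neighbouring calls against 10000 shuffles.

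Other settings fixed beforehand were DESeq2 1.42.0, RLE size factors, no low-count filter, the number in the animal code as a block, limma voom with sample weights, 1 surrogate variable (sva 3.50.0), a fit of the compared groups alone, no rat block, and leaving out each library. Settings chosen after seeing the data removed the trend with gene density, left out mitochondrial features, thinned all libraries of a region to one depth, or computed the mitochondrial share on features of 200 nt or more and without each library.

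The procedure was tested on simulated counts with the group sizes, depths and trended dispersion of the tables. In them 200 genes with a mean of at least 20 counts were changed. The spread of single genes around the trend and differences shared across a library were not simulated. Recovery and false calls may therefore be worse in the real data. For NAc females it recovered 49.3% of 1.5-fold, 85.1% of 2-fold and 98.5% of 4-fold changes, with 6 false calls among 13004 genes. For VTA females it recovered 2.99%, 50.7% and 92.4%, with 3 false calls among 14128 genes. For the difference between sexes, recovery at 2-fold was 53.7% in the NAc and 14.9% in the VTA. In simulated males with no changed gene, edgeR made 0 calls in either region.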

Results

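Gene expression was measured by RNA sequencing in the NAc, a striatal area of the reward system, and in the VTA, the midbrain area that sends dopamine axons to it. The rats had received fentanyl, an opioid agonist, or saline, and the series title places them in opioid withdrawal and in a choice between fentanyl and food. NAc groups held 4 fentanyl and 3 saline rats of each sex, and VTA groups held 3 fentanyl and 2 saline rats of each sex. Total counts per library ran from 3.46 M to 5.01 M in the NAc and from 4.49 M to 6.3 M in the VTA. Mitochondrial features took 22.1% to 36.7% of the counts in NAc libraries and 17.6% to 26.9% in VTA libraries. Genes with a count numbered 18008 to 18882 per NAc library and 18046 to 19475 per VTA library. The files do not pair gene IDs with names, so genes are given by ID and position, on a build not given in the sources used here.

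The first question was which genes differed between fentanyl and saline rats in the NAc, and in females many did. Of 13248 genes tested, 1066 rose and 722 fell in fentanyl females (n = 4) against saline females (n = 3), 1788 in all at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The median log2 fold change was 0.61 among those that rose and -0.55 among those that fell; 208 rose and 77 fell by more than 2-fold. ENSRNOG00000020951 (chromosome 10, 90296141 to 90312386) rose from 0.215 ± 0.372 to 17.2 ± 17.0 CPM (mean ± SD), 3 counts against 227. That is 76.6-fold by counts, with a counting interval of 25.9 to 374 and an adjusted p of 0.0417. ENSRNOG00000047321 (chromosome 10, 15589364 to 15590220) rose from 8.78 ± 2.31 to 156 ± 91.1 CPM, a log2 fold change of 4.14 ± 1.20 (SE), with an adjusted p of 0.0461. ENSRNOG00000055178, a single-exon feature (chromosome 7, 101138549 to 101138860), fell from 2.09 ± 0.361 to 0.412 ± 0.205 CPM. Its log2 fold change was -2.31 ± 0.63, with an adjusted p of 0.0174. ENSRNOG00000050933, another single-exon feature (chromosome 17, 43821225 to 43821536), fell from 5.69 ± 1.96 to 1.33 ± 1.06 CPM, a log2 fold change of -2.02 ± 0.51 with an adjusted p of 0.0111. On the first principal component of the NAc libraries (20.6% of the variance) fentanyl females lay at 5.24 to 33.7, males at -9.74 to 4.35 and saline females at -15.1 to -11.3. The library at 33.7 was fentanyl replicate 1, without which 1437 genes passed. The count of 1788 was 755 without saline replicate 1, 1003 without saline replicate 2, 923 without saline replicate 4 and 1102 with the female groups alone in the fit. The call of ENSRNOG00000020951 ended without fentanyl replicate 1 or 7 or any saline library, with no low-count filter, with the replicate block, by voom, at one depth and with the female groups alone (10 of 17 alternatives, adjusted p 0.00321 to 0.164 over all 17). That of ENSRNOG00000047321 ended without fentanyl replicate 1, 2 or 7 or any saline library, with no low-count filter, with the replicate block, by voom and with 1 surrogate variable (10 of 17, 0.000496 to 0.144). The call of ENSRNOG00000055178 ended without saline replicate 1 or 2 and with the replicate block (0.016 to 0.143) and that of ENSRNOG00000050933 without saline replicate 2 (0.000111 to 0.0689).

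**Figure D1:**
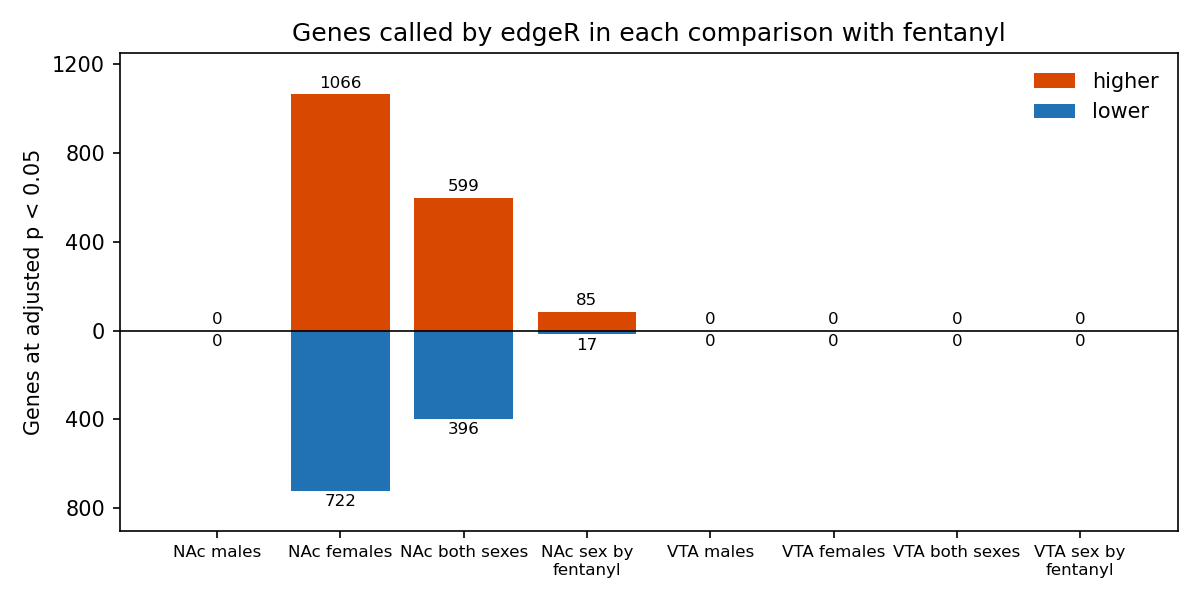
Bars give the number of genes at an adjusted p under 0.05 (edgeR) in each comparison, those higher with fentanyl above 0 and those lower below 0; for the difference between sexes, higher means a larger effect in females. NAc females have 1066 and 722, NAc males and the 4 VTA comparisons have 0.

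Mitochondrial features and X-linked genes stood apart from other genes in the NAc of females at the preset correlation of camera; 3 of 26 sets did so, and 0 of 26 with an estimated correlation. Of the 13 mitochondrial features of 200 nt or more, 7 rose, 0 fell and 6 did not pass the test by edgeR. Of these features, 10 had an unadjusted p under 0.05 and 12 had a positive log2 fold change, with a median of 0.64. Of the 16 mitochondrial features under 100 nt, 3 rose and 13 did not pass, with a median of 1.28. The adjusted p by camera was 0.000123 for the longer and 0.0167 for the shorter features, and 0.352 and 0.524 with an estimated correlation. Mitochondrial features took 31.6 ± 3.54% of counts in fentanyl females and 24.5 ± 2.12% in saline females, and all 4 fentanyl libraries lay above all saline libraries. The exact two-sided permutation p was 0.0286, the smallest that 35 regroupings can give, and 0.09 after adjustment. Counts outside the mitochondrial chromosome were 2.24 M to 3.26 M in fentanyl and 3.30 M to 3.75 M in saline females (exact two-sided permutation p = 0.0571, adjusted 0.343).

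Of 474 X-linked genes, 70 rose, 16 fell and 388 did not pass the test in NAc females. Of them, 65.4% had a positive log2 fold change, with a median of 0.16. The adjusted p by camera was 0.00995, and 0.212 with an estimated correlation. Without saline replicates 1, 2 and 4, 31, 41 and 39 X-linked genes rose and 10, 9 and 7 fell, with medians of 0.153, 0.135 and 0.164. Without 1 fentanyl library 55 to 80 rose. Chromosome 2 was as lopsided in its calls, with 94 of 907 genes up and 16 down, 60.3% positive and a median of 0.09; its adjusted p was 0.0718 by camera. By fry 12 of the 26 sets had an adjusted p under 0.05, 11 of them chromosomes, some up and some down. The values were 0.00399 for chromosomes 2 (up) and 7 (down), 0.0075 for X, and 0.0281 and 0.121 for the longer and shorter mitochondrial features. Calls in each direction were spread unevenly over sparse and dense parts of the genome, while most genes in both did not pass the test. In the fifth of genes with the fewest neighbours 270 rose and 106 fell, and in the fifth with the most neighbours 113 rose and 240 fell; the median log2 fold changes were 0.07 and -0.12. The rank correlation of log2 fold change with local density was -0.177 across genes in females and 0.0012 in males; genes are not independent replicates. Of 409 genes at least 4-fold higher in the NAc than in the VTA, 30 rose and 53 fell in NAc females (camera adjusted p = 0.15). Of 174 measured genes at least 4-fold higher in the VTA, 6 rose and 2 fell (camera adjusted p = 0.386). These region sets were chosen on the same libraries and are not independent evidence. Of 420 single-exon features under 500 nt outside the mitochondrial chromosome, 49 rose and 27 fell (camera adjusted p = 0.609).

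**Figure D2:**
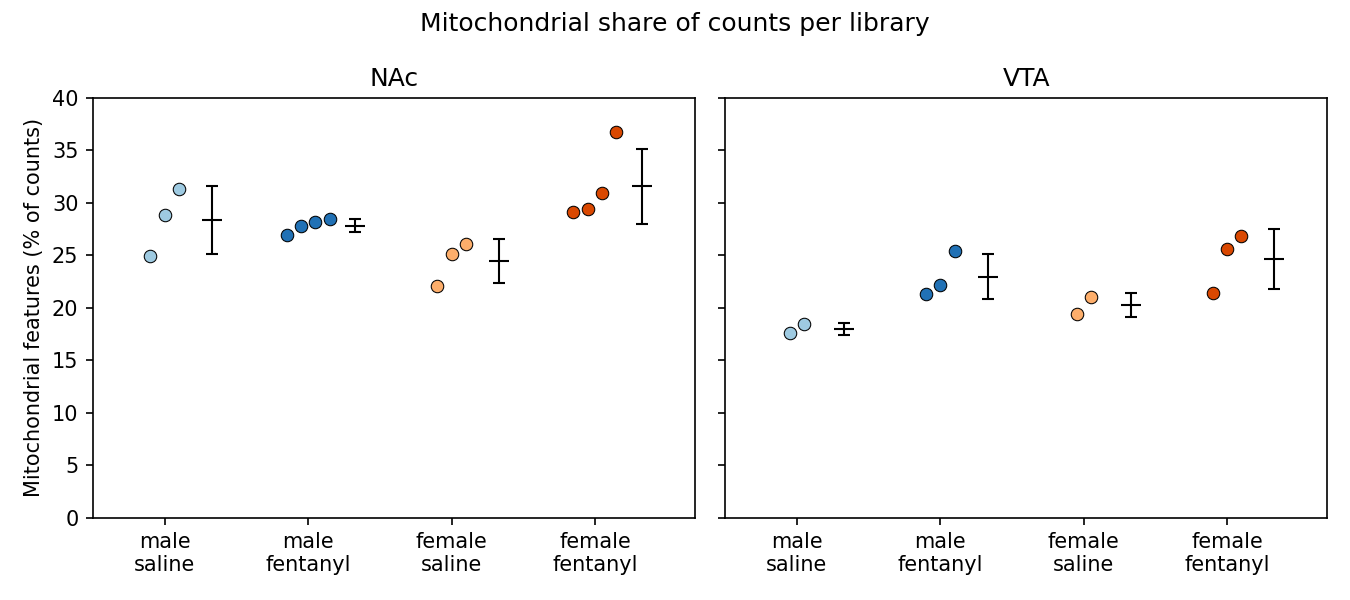
Points are libraries, and the bar beside each group is the mean ± SD of the mitochondrial share of counts in percent. The fentanyl females of the NAc average 31.6% against 24.5% in saline females; in the VTA the fentanyl libraries of each sex lie above the saline libraries of that sex.

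**Figure D3:**
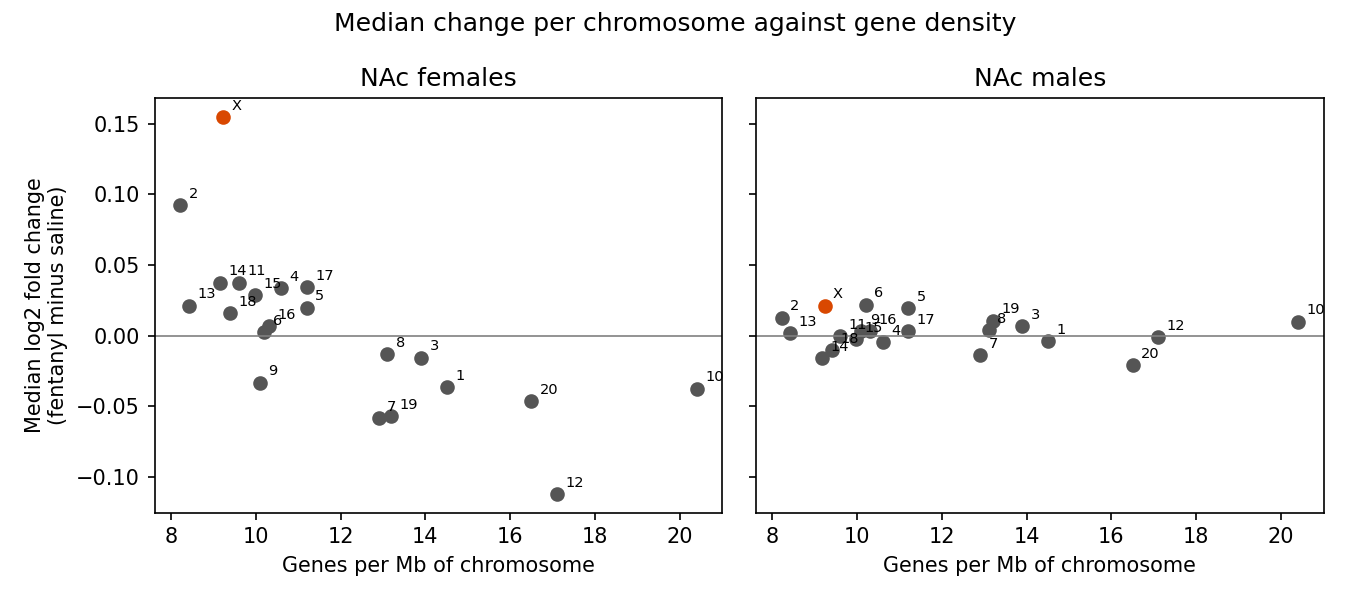
Each point is a chromosome, with genes per Mb on the horizontal axis and the median log2 fold change (fentanyl minus saline) on the vertical axis, for NAc females and males; the X chromosome is drawn in orange. The rank correlation over 21 chromosomes is -0.796 in females and -0.0604 in males, and chromosomes are not independent replicates.

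In the NAc of males (n = 4 and 3), edgeR called 0 of 13248 genes, while 850 genes (6.42%) had an unadjusted p under 0.05 and DESeq2 called 6. The lowest adjusted p by edgeR was 0.322. ENSRNOG00000015055 (chromosome 9, 85237458 to 85243001) had 84.9 ± 2.63 CPM with fentanyl and 58.4 ± 7.17 with saline, a log2 fold change of 0.54 ± 0.11 and an adjusted p of 0.322. ENSRNOG00000033261 (chromosome 15, 18399515 to 18415965) had 1090 ± 266 and 559 ± 91.9 CPM, a log2 fold change of 0.96 ± 0.20 and an adjusted p of 0.419. ENSRNOG00000034066 (chromosome 8, 44990014 to 44993179) had 119 ± 20.7 and 186 ± 31.5 CPM, with an adjusted p of 0.322; in females it fell from 248 ± 13.9 to 108 ± 8.45 CPM, with an adjusted p of 6.25e-06. ENSRNOG00000015750 (chromosome 7, 126420656 to 126465723) had 6.39 ± 2.72 and 14.9 ± 3.75 CPM, with an adjusted p of 0.419. Mitochondrial features took 27.8 ± 0.661% of counts with fentanyl and 28.4 ± 3.23% with saline (exact two-sided permutation p = 0.714). The 474 X-linked genes had a median log2 fold change of 0.02 in males. By DESeq2 these 4 genes had adjusted p of 0.0222, 0.000996, 0.0136 and 0.0402, with ranges over all alternatives of 0.0088 to 0.999, 0.000996 to 0.999, 3.36e-05 to 0.999 and 0.00117 to 0.999. The count was 46 with no low-count filter, 2 with the male groups alone and 2 without fentanyl replicate 3, and the difference in mitochondrial share, -0.523 percentage points, was 0.953 without saline replicate 3.

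The title asks for effects that differ by sex, which the difference of the female and male effects tests directly. In the NAc 102 genes differed, 85 with a higher effect in females and 17 with a lower one (edgeR, adjusted p under 0.05), with median differences of 1.01 and -0.86 on the log2 scale. ENSRNOG00000029461, a single-exon feature (chromosome 14, 43694183 to 43694611), had 7.64 ± 1.19 CPM in fentanyl and 1.79 ± 1.23 in saline females, and 4.65 ± 0.753 and 6.96 ± 1.29 in males, a difference of 2.67 ± 0.49 with an adjusted p of 0.00957. ENSRNOG00000051300 (X chromosome, 73757664 to 73758388) had 7.06 ± 1.74 and 1.34 ± 0.63 CPM in females and 4.70 ± 1.09 and 5.38 ± 1.60 in males, a difference of 2.56 ± 0.48 with an adjusted p of 0.0125. ENSRNOG00000020835 (chromosome 1, 84328114 to 84338483) had 4.59 ± 1.40 and 10.7 ± 2.18 CPM in females and 8.20 ± 0.36 and 5.80 ± 0.855 in males, a difference of -1.72 ± 0.35 with an adjusted p of 0.022. ENSRNOG00000058484, on an unplaced scaffold, had a difference of -2.38 ± 0.57 with an adjusted p of 0.0483. Of the mitochondrial features of 200 nt or more, 1 of 13 passed this test and all 13 had a positive difference (camera adjusted p = 3.99e-05, and 0.306 with an estimated correlation). The X-linked genes had a median difference of 0.11 (camera adjusted p = 0.0216, and 0.208 with an estimated correlation). The effect on the mitochondrial share was 7.64 percentage points higher in females than in males (exact two-sided permutation p = 0.0129 over 1400 regroupings, not adjusted). In the VTA that difference was -0.55 points (exact two-sided permutation p = 0.817 over 120 regroupings). The count of 102 was 59, 43 and 43 without male fentanyl replicates 1, 3 and 7, and 167 and 299 without female fentanyl replicates 2 and 8. It was 20 without male saline replicate 3, and 23, 49 and 41 without female saline replicates 1, 2 and 4. It was 256 by DESeq2, 388 with no low-count filter, 236 with the replicate block and 162 by voom. The adjusted p over all alternatives was 2.79e-05 to 0.0603 for ENSRNOG00000029461 (lost without male saline replicate 3) and 0.000452 to 0.0903 for ENSRNOG00000051300 (lost without male saline replicate 3 or female saline replicate 1). It was 0.0021 to 0.0961 for ENSRNOG00000020835 (lost without male saline replicate 3 or female saline replicate 1 or 4, and at equal depth) and 0.0316 to 0.144 for ENSRNOG00000058484 (lost in 11 of the 14 fits without 1 library, all but those without male fentanyl replicate 2 and female fentanyl replicates 7 and 8, and with the replicate block, 1 surrogate variable, the density trend removed and at equal depth).

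As a mean over both sexes in the NAc (n = 8 and 6), 599 genes rose and 396 fell with fentanyl, 995 in all (edgeR, adjusted p under 0.05), with median log2 fold changes of 0.42 and -0.41. ENSRNOG00000010529 (chromosome 1, 56653938 to 56683731) rose from 0.329 ± 0.356 to 2.29 ± 0.949 CPM, a log2 fold change of 2.69 ± 0.56 with an adjusted p of 0.00688. ENSRNOG00000013615 (chromosome 1, 260289589 to 260321320) rose from 0.484 ± 0.177 to 1.94 ± 1.09 CPM, with an adjusted p of 0.0159. ENSRNOG00000015750, on chromosome 7, fell from 15.2 ± 2.5 to 7.20 ± 2.29 CPM, a log2 fold change of -1.07 ± 0.18 with an adjusted p of 0.0022; it was below its saline range in each sex. ENSRNOG00000061185 (chromosome 17, 43776050 to 43776460) fell from 7.14 ± 1.63 to 3.71 ± 0.95 CPM, with an adjusted p of 0.00954. Of the 1788 genes called in females, 68.2% had the same sign in NAc males, and 8 of the 35 splits of the male libraries gave a share as high. Over those genes, which were chosen on the female libraries, on a scale from 0 (saline females) to 1 (fentanyl females), male fentanyl libraries lay at 0.641 ± 0.11 and male saline libraries at 0.508 ± 0.17. The count of 995 was 544 without male fentanyl replicate 2, 518 and 315 without male saline replicates 1 and 4, and 455, 600 and 534 without female saline replicates 1, 2 and 4. It was 341 with the replicate block, 281 of them among the 995. With the replicate block 3 of the 4 genes did not pass: ENSRNOG00000010529 (0.058, the highest of its range from 8.97e-05), ENSRNOG00000061185 (0.0681, the highest of its range from 0.00153) and ENSRNOG00000013615 (0.132, the highest of its range from 0.00523). The last also failed without male saline replicate 4 (0.0623).

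**Figure D4:**
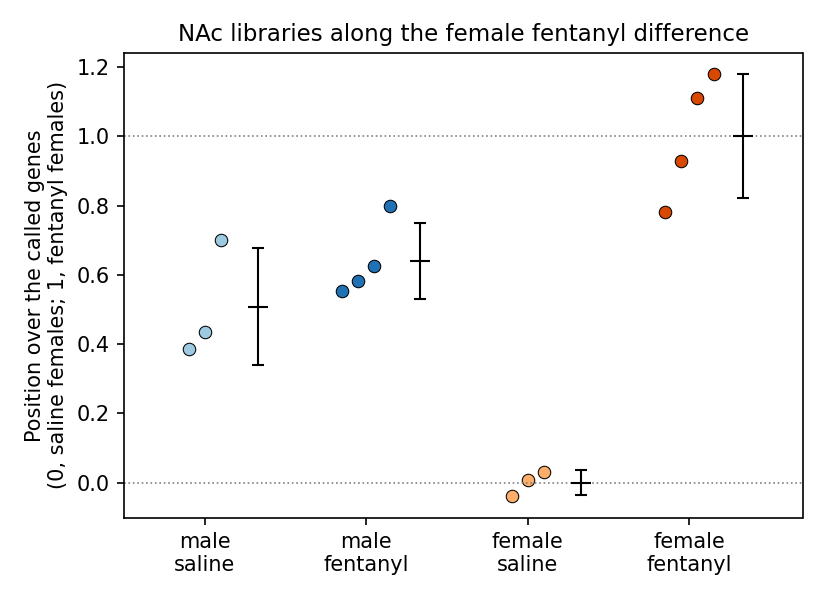
Points are NAc libraries placed over the genes called in females, on a scale where saline females average 0 and fentanyl females average 1; bars are mean ± SD. The genes were chosen on the female libraries, which places the female groups at the ends. Male saline libraries lie from 0.387 to 0.702 and male fentanyl libraries from 0.554 to 0.799.

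Saline females differed from saline males in the NAc (n = 3 and 3) at 50 genes, 10 higher and 40 lower in females (edgeR, adjusted p under 0.05). X-linked genes made up 5 of the higher and 1 of the lower, 6 of the 7 tested Y-linked genes were lower, and 5 other genes were higher and 33 lower. ENSRNOG00000051257 (X chromosome, 74333329 to 74337975, minus strand) had 214 ± 5.73 CPM in females and 0.346 ± 0.115 in males, a log2 fold change of 9.13 ± 0.26 with an adjusted p of 6.08e-18. ENSRNOG00000037911, which spans it on the plus strand (74304292 to 74345507), had 152 ± 10.8 and 2.32 ± 0.489 CPM, a log2 fold change of 6.03 ± 0.23 with an adjusted p of 4.61e-15. ENSRNOG00000060617 (Y chromosome, 989240 to 1206096) had 279 counts in males and 0 in females, at least 126-fold lower. ENSRNOG00000060437 (Y chromosome, 66972 to 70369) had 268 and 0, at least 121-fold lower. The count of 50 was 10 without male saline replicate 3 and 12, 16 and 17 without female saline replicates 1, 2 and 4; it was 13 with the replicate block, 120 by DESeq2 and 210 with no low-count filter. The rank correlation of this sex difference with local gene density was 0.207 across genes. Fewer genes passed between the sexes with fentanyl than with saline in all 16 fits of 3 rats against 3: the median number outside X and Y was 1 between fentanyl females and males (0 to 26) and 39.5 between saline females and males (23 to 86).

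In the VTA of males (n = 3 and 2) edgeR called 0 of 14400 genes, where 648 had an unadjusted p under 0.05 and DESeq2 called 7. In VTA females (n = 3 and 2) it called 0, where 1098 had one and DESeq2 called 37. Female fentanyl replicate 2 lay at 48.9 on the first principal component of the VTA libraries (26.2% of the variance) and the other 9 libraries at -22.1 to 13.2. As a mean over both sexes it called 0, with 1271 at an unadjusted p under 0.05 and 39 by DESeq2, and for the difference between sexes 0, with 476 and 1. All 13 mitochondrial features of 200 nt or more had positive log2 fold changes in each sex, with medians of 0.45 in males and 0.39 in females, and as a mean over both sexes all 13 had an unadjusted p under 0.05. Their adjusted p by camera was 4.75e-09 in males and 2.22e-06 in females, and 0.694 and 0.785 with an estimated correlation. The mitochondrial share was 23.0 ± 2.17% with fentanyl and 18.0 ± 0.575% with saline in males, and 24.6 ± 2.88% and 20.2 ± 1.14% in females. Exact two-sided permutation p were 0.1 and 0.2, where 10 regroupings cannot give less than 0.1, and 0.03 over both sexes, 0.09 after adjustment; all 6 fentanyl libraries lay above all saline libraries. Of 327 measured genes at least 4-fold higher in the NAc, the median log2 fold change was -0.21 in VTA females (camera adjusted p = 0.00153, and 0.785 with an estimated correlation) and 0.03 in VTA males (0.961 and 0.996). The 503 X-linked genes had medians of -0.02 in VTA females and 0.03 in VTA males. Without 1 library the counts of called genes were 11 and 6 in females (fentanyl replicate 2, saline replicate 1) and 1 each without female fentanyl replicates 1 and 7. For both sexes they were 2 without female saline replicate 1 and 1 each without male fentanyl replicates 1 and 2 and female fentanyl replicates 2 and 7. For the difference between sexes they were 5 without female saline replicate 1 and 1 without male fentanyl replicate 2. With no low-count filter the counts were 114 in males, 418 in females, 499 over both sexes and 109 for the difference between sexes. With 1 surrogate variable they were 5 in females and 2 over both sexes, and with the compared groups alone 2 in males and 5 in females. The replicate block gave 1 over both sexes and voom 1 in males.

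Single genes of the VTA are given as values, since none passed the edgeR test with fentanyl. Those given for fentanyl against saline were all called by DESeq2, and by edgeR with no low-count filter. They were picked for the smallest p on the same libraries, so these calls are not independent evidence. Each was called in at most 4 of its alternatives, such as 4 of 15 for ENSRNOG00000020951 and 2 of 15 for ENSRNOG00000020514 in females. For the difference between sexes DESeq2 called only ENSRNOG00000045989, given below. The rule also picked ENSRNOG00000005387 (X chromosome, difference 1.53 ± 0.32), ENSRNOG00000042731 (-1.35 ± 0.33) and ENSRNOG00000009329 (chromosome 10, -0.746 ± 0.187). With no low-count filter edgeR called the first and second of these (adjusted p = 3.41e-05 and 0.00165). In females ENSRNOG00000020951 had 272 counts with fentanyl and 2 with saline, 108-fold by counts with an interval of 29.6 to 894 (adjusted p = 0.132 by edgeR and 0.000124 by DESeq2). It passed with 1 surrogate variable (0.0231) and without fentanyl replicate 2 (0.00513), in a range over all alternatives of 6.95e-21 to 1. ENSRNOG00000045989 (chromosome 10, 15577249 to 15577977) had 11.7 ± 1.74 and 1.84 ± 0.223 CPM in females (adjusted p = 0.132, DESeq2 0.000174, range 9.66e-06 to 1). Its effect differed between sexes by 3.60 ± 0.55 on the log2 scale (adjusted p = 0.251, DESeq2 0.00351, range 6.7e-05 to 1). ENSRNOG00000042731 (chromosome 4, 153330069 to 153350446) had 18.2 ± 2.37 and 52.1 ± 11.2 CPM in females (adjusted p = 0.132, DESeq2 0.000174, range 1.04e-10 to 1). Both passed without fentanyl replicate 2 (0.0378 and 0.0459). ENSRNOG00000020514 (chromosome 1) had 11 ± 2.22 and 23.4 ± 4.35 (adjusted p = 0.44, DESeq2 0.0466, range 0.00187 to 1). In males the mitochondrial feature ENSRNOG00000033932 (5010 to 5078) had 67.8 ± 14.8 and 31.7 ± 2.90 CPM (adjusted p = 0.606, DESeq2 0.0113, range 3.94e-05 to 1). ENSRNOG00000001785 (chromosome 11, 82194657 to 82252139) had 37.2 ± 6.50 and 94.0 ± 8.92 CPM (adjusted p = 0.466, DESeq2 0.00201, range 1.47e-09 to 1), and passed by voom (0.0186) and with the male groups alone (0.042). Over both sexes the mitochondrial feature ENSRNOG00000032997 (14062 to 14130) had 170 ± 34.1 and 84.7 ± 7.99 CPM (adjusted p = 0.171, DESeq2 2.8e-06, range 7.31e-12 to 0.896), and passed with the replicate block (0.00582) and without female fentanyl replicate 7 (0.000692). ENSRNOG00000054549 (chromosome 20, 12842884 to 12870497) had 25.3 ± 4.70 and 42.6 ± 3.55 (adjusted p = 0.235, DESeq2 0.00309, range 4.43e-05 to 0.896). Of the genes called in NAc females, 1773 were measured in the VTA; 73.4% had the same sign in VTA females and 79.0% in VTA males, each the highest of 10 splits, which cannot give a share under 0.1. The highest other splits gave 72.5% and 71.3%. VTA and NAc libraries come in part from the same rats. Saline females and males of the VTA (n = 2 and 2) differed at 8 genes, 3 X-linked genes higher and 5 Y-linked genes lower in females (edgeR, adjusted p under 0.05). Among them ENSRNOG00000051257 had 140 ± 8.79 and 0.435 ± 0.615 CPM, with an adjusted p of 8.89e-07, and ENSRNOG00000060437 was at least 85.2-fold lower in females, with 0 counts against 262. The count was 15 without female saline replicate 1, and 115 with no low-count filter.

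Within the 10 rats that gave both regions, 8515 of 12901 genes differed between the VTA and the NAc, 4193 higher in the VTA and 4322 higher in the NAc (edgeR, adjusted p under 0.05). ENSRNOG00000012283 (chromosome 16, 68860018 to 68866718) had 138 ± 70.4 CPM in the VTA and 0.176 ± 0.319 in the NAc, a log2 fold change of 9.31 ± 0.31 with an adjusted p of 5.46e-12. ENSRNOG00000020410 (chromosome 1, 216073031 to 216080287) had 947 ± 545 and 2.25 ± 1.08 CPM, a log2 fold change of 8.47 ± 0.65 with an adjusted p of 1.43e-06. ENSRNOG00000047891, a single-exon gene (chromosome 6, 69971227 to 69974037), had 1.83 ± 0.737 CPM in the VTA and 364 ± 67.8 in the NAc, a log2 fold change of -7.61 ± 0.13 with an adjusted p of 1.76e-18. ENSRNOG00000028348 (chromosome 2, 260574190 to 260596777) had 0 counts in the VTA and 384 in the NAc, at least 196-fold lower. For the difference of the fentanyl effect between regions edgeR called 0 of 14795 genes in males, with 493 at an unadjusted p under 0.05 and 1 by DESeq2, and 0 in females, with 1517 and 30. With no low-count filter edgeR called 28 in males and 346 in females. In females the count was 1 without fentanyl replicate 1 or saline replicate 1.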

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

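Chosen only after the result was seen were the tests of the saline females alone, of splits at equal depth, of mitochondrial yield, of short RNAs in NAc females and of X dosage, and the counts of splits for NAc males and for the VTA over both sexes.

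Of 48 groups of values tested for a sample far from the others, 7 had one, where chance gives about 1 in 20. The far samples, in CPM, were 10.3 for ENSRNOG00000020951, 244 for ENSRNOG00000047321, 2.77 for ENSRNOG00000055178 and 0.246 for ENSRNOG00000051257 in male fentanyl NAc libraries, and 3.77 for ENSRNOG00000013615, 2.66 for ENSRNOG00000061185 and 0.345 for ENSRNOG00000060617 in female fentanyl NAc libraries. The first 2 values came from the same library, male fentanyl replicate 7. The values of 0.246 and 0.345 CPM are near the floor, about 1 read at this depth, where the rate of 1 in 20 need not hold.

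The fentanyl effect differed between females and males of the NAc at 102 genes by the test of the difference itself, and for the mitochondrial share by 7.64 percentage points (exact two-sided permutation p = 0.0129, not adjusted). The shares were 24.5% in saline females and 28.4% in saline males, and 31.6% and 27.8% with fentanyl. The low saline females are thus part of this difference in share. For the genes, 4 of 100 splits gave as many, and the highest other gave 504, several times the real count. A split of that size points to a structure of the samples. The 3 other splits as high as the real one (504, 223 and 187) kept all females in their real groups and moved 2 of the 4 fentanyl males, so the female difference itself is part of what they call.

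The 1788 calls in NAc females were not reached by any other of the 35 splits of these libraries (1 of 35 with the real one, highest other 1249). That argues against chance assignment of rats to groups as the whole account, though 35 splits cannot give a share under 0.0286. The only other splits with calls (1249, 234, 89 and 3) put the 3 saline females together with 1 fentanyl female. Calls thus appeared only where the saline females stayed together. Saline females alone standing apart from all other rats stays open. Outside X and Y a median of 1 gene differed between fentanyl females and males and 39.5 between saline females and males (16 fits, 3 against 3). Yet on the first principal component of the NAc libraries the fentanyl females (5.24 to 33.7) lay beyond all males (-9.74 to 4.35) on one side and the saline females (-15.1 to -11.3) on the other. The nearest fentanyl female and male were close, at 5.24 and 4.35. On the second component (14.3% of the variance) the fentanyl females (-12.4 to 1.76) lay between the saline females (-15.9 to -15.6) and the males (6.42 to 15.1). The components thus do not decide the question. A trend with gene density is argued against as the whole cause, since 80.5% of the genes were still called in the same direction with it removed. At equal depth 77.0% stayed called, between the bounds of 50% and 80% set beforehand, against 82.1% with all libraries thinned by one factor. A difference in depth is argued against as the whole cause by the 35 splits at equal depth, where the real one called 1491 genes and the highest other 1016. A sex difference in saline rats that fentanyl reduces, and differences in dissection, handling or estrous cycle among the 3 saline females, stay open and were not told apart.

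Mitochondrial shares were higher in fentanyl than in saline rats in NAc females and in both sexes of the VTA, but adjusted p were 0.09, 0.15 and 0.24, and camera with an estimated correlation gave adjusted p of 0.352, 0.694 and 0.785. In the VTA edgeR called no mitochondrial feature, with all 13 longer ones at an unadjusted p under 0.05 over both sexes. DESeq2 called some there, such as ENSRNOG00000032997 (adjusted p = 2.8e-06 over both sexes) and ENSRNOG00000033932 (0.000394). In NAc females a higher yield of all mitochondrial RNA would move the 13 longer features alike, yet the SD of their log2 fold changes was 2.08 times the median standard error, just over the bound of 2 that was chosen after the values were seen. In the VTA the same ratio was 0.746. The standard error includes variation that the features share (estimated correlation 0.776), so a low ratio does not show that they moved alike. A common rise, from yield or from the tissue, stays open there. Better recovery of very short RNAs is argued against in the VTA, since short features outside the mitochondrial chromosome lay below longer ones, by -0.227 on the log2 scale (interval -0.352 to -0.165), and by -0.156 (-0.283 to -0.0244) over the 90 of 128 features outside runs of neighbours; features are not independent. In NAc females it stays open: the 81 short features outside runs differed from longer ones by 0.0859 (-0.252 to 0.302), too wide an interval to decide. A change in the tissue and a difference in sample handling between treatments stay open, and neither was tested.

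X-linked genes stood apart upward in NAc females with an adjusted p of 0.00995 by camera but 0.212 with an estimated correlation, and 388 of 474 did not pass the test; chromosome 2 had 94 genes up and 16 down. Gene density is argued against only as the whole cause: with the density trend removed the X median was 0.118, down from 0.16. Of 10000 autosomal sets matched on density and expression, 100% had a median at or below that of X (matched median 0.0136). Those sets were drawn gene by gene over all autosomes. Their spread ignored the correlation among genes of a chromosome (estimated at 0.0189 for X), so the 100% overstates the difference. A change of X dosage stays open: the 65.4% of X-linked genes with a positive log2 fold change is the observation itself and favours no cause. The VTA of females had an X median of -0.02, and a change of cell types was not tested.

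For the other counts of called genes, chance is argued against as the whole account for the NAc over both sexes (1 of 100 splits, real 995, highest other 498). The other splits with the most calls (498, 284, 227 and 153) kept all females in their real groups and moved 2 of the 4 fentanyl males. The female difference is thus part of what this test calls. It is not separate evidence for an effect in both sexes. Chance is also argued against for the regions (1 of 100, real 8515, highest other 0). For NAc males (35 of 35; real 0, highest other 5) and the VTA over both sexes (100 of 100; real 0, highest other 18) the real count of 0 by edgeR lets every split count as high, so these numbers say nothing about chance; unadjusted p under 0.05 numbered 850 and 1271, and DESeq2 called 6 and 39. For the sex difference in saline NAc the 10 splits are too few for a share under 0.05 (1 of 10; real 50, highest other 1).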

How the results depend on the processing

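The alternatives without the density trend, without mitochondrial features, at one depth, and for the mitochondrial share were chosen after seeing the data. Counts equal to the reported one or within 1.5 times it were found for 13 of 13 comparisons with RLE size factors. The same held for 10 of 10 each with the density trend removed, without mitochondrial features and thinned to one depth, and 3 of 3 without the rat block. These include comparisons with 0 calls in both fits, which say little: NAc males, fentanyl in the VTA and the region difference of the effect. By DESeq2 the counts that moved further were 6 in NAc males, 256 for the NAc sex difference of the effect, 120 for saline sex in the NAc, 7 in VTA males, 37 in VTA females, 39 over both sexes of the VTA, 1 for the VTA sex difference of the effect, and 1 and 30 for the region difference of the effect in males and females. With no low-count filter they were, in the same order, 46, 388, 210, 114, 418, 499, 109, 28 and 346, and 115 for saline sex in the VTA; of the 418, 406 were among the genes that pass the filter. With the number in the animal code as a block, whose pairing of rats could not be told, they were 341 over both sexes of the NAc. They were 236 for the NAc sex difference of the effect, 13 for saline sex in the NAc and 1 over both sexes of the VTA. By voom they were 162 for the NAc sex difference of the effect and 1 in VTA males. With 1 surrogate variable they were 5 in VTA females and 2 over both sexes of the VTA. With the compared groups alone they were 2 in NAc males, 1102 in NAc females, 2 in VTA males and 5 in VTA females. The cause was not tested for these, except that fewer samples estimate the spread in the last case. NAc females gave 1425 to 2072 calls under the other alternatives that keep all libraries, the lowest with the replicate block and the highest with no filter.

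Leaving out each library in turn gave 755 to 2018 calls in NAc females, 315 to 1299 over both sexes, 20 to 299 for the sex difference of the effect, 10 to 57 for saline sex and 0 to 2 in NAc males. In the VTA it gave 0 to 11 in females, 0 in males, 0 to 2 over both sexes, 0 to 5 for the sex difference of the effect and 8 to 15 for saline sex. For the regions it gave 8156 to 8484, and 0 to 1 in females and 0 in males for the region difference of the effect. Where a VTA group is left with 1 rat, it is assumed to vary like the other groups. The mitochondrial share difference in NAc males ran from -2.25 to 0.953 and changed sign without male saline replicate 3; in NAc females it ran from 5.4 to 7.96 and over both sexes of the VTA from 4.07 to 5.5. Among single genes, 627 settings kept the side of the threshold, 50 lost a call, 47 gained one and 0 reversed. The 4 planned gene list tests were not run, since no ID could be matched. In simulated data 2.99% of 1.5-fold changes were recovered in VTA females and 49.3% in NAc females; the VTA libraries are deeper but come from fewer rats and had a biological coefficient of variation of 20.3%, against 13% in the NAc.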

Other observations

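The features and windows described here were chosen only after the data were seen. A run of 34 features under 100 nt lies on the plus strand of chromosome 6 (133662524 to 133877205). In NAc females 6 of them fell by edgeR, 30 had a negative log2 fold change, and the median was -0.50; the other 81 short features had a median of 0.09. The mean log2 CPM of the run was 2.5 ± 0.279 in fentanyl and 2.95 ± 0.195 in saline females (exact two-sided permutation p = 0.114 over 35 splits), and 2.8 ± 0.234 and 2.75 ± 0.0913 in males (p = 0.771, exact). In the VTA the median was -0.59 in females and -0.27 in males.

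Genes called in NAc females lay next to each other more often than shuffled calls. There were 172 adjacent pairs with one direction, against a mean of 123 and a highest of 164 over 10000 shuffles (permutation p = 1e-04, the smallest they can give). The shuffles, here and in the scan below, did not keep local gene density, which the calls followed. Neighbours called alike through density or shared reads were thus not told apart. On chromosome 7, 13 of 47 genes between 11013681 and 11998973 fell (scan p = 0.003 by permutation), 7 of them with the density trend removed. On chromosome 15, 6 of 9 genes between 37835580 and 38276159 rose (scan p = 0.032 by permutation), 5 of them with the density trend removed.

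On chromosome 10, ENSRNOG00000047321 and ENSRNOG00000045989 are neighbours, and ENSRNOG00000020951 lies farther away. In VTA females ENSRNOG00000047321 had 301 ± 75 CPM with fentanyl and 15.8 ± 2.60 with saline (edgeR adjusted p = 0.507), and in VTA males 39.1 ± 35.6 and 49.5 ± 33.2. The difference between sexes in the NAc had adjusted p of 0.514 to 0.606 for these 3 features by edgeR. All 3 had higher means with fentanyl than with saline in females of both regions. Differences in dissection or in cell types between the punches were not tested for them.

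Features of the Y chromosome had 3.64 ± 0.407 counts per M counts outside the mitochondrial chromosome in fentanyl and 6.31 ± 0.646 in saline females of the NAc. These were 9 to 11 counts per fentanyl library and 21 to 26 per saline library. Where these few reads in females came from was not tested, and they are not taken as expression of Y-linked genes. A difference in sample handling stays open here too.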
